A study of Schizosaccharomyces pombe
Saccharomyces cerevisiae with 8 samples.

How the data were processed

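Budding yeast (Saccharomyces cerevisiae, mating type alpha) expressed the plant auxin receptor OsTIR1 and carried degron tags on Med14 and Med17, structural subunits of the Mediator coactivator, so that auxin triggers removal of both proteins. Per the labels' protocols, cultures received 500 µM auxin (3-indole acetic acid) or the carrier DMSO for 30 min and then 5 mM 4-thiouracil for 6 min, and were mixed with fission yeast (Schizosaccharomyces pombe) cells at 1 part to 3 parts before RNA was extracted. Total RNA and the purified 4-thiouracil-labelled, newly synthesized RNA were each sequenced from 2 DMSO and 2 auxin samples, 8 libraries in 4 groups. Libraries were stranded and ribosomal RNA was depleted, per the labels' protocols. The genome build was sacCer3 and bcl2fastq was version 2.17.1.14, per the submitters' processing notes. The aligner, the counting tool and its use of strand were not given in the sources used here. The series design calls the samples of each group biological replicates, labelled 1 or 2.

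There was 1 table per RNA fraction. Raw counts per S. cerevisiae feature were deposited as whole numbers. The authors also gave a normalized signal per library, which the values show to be the raw count divided by 1 size factor per library, and the same divided again by transcript length in kb, per the file headers. What the size factors were computed from was not given in the sources used here. A log2 fold change, auxin over DMSO, was deposited for each feature, per the file headers. The authors' p-values, raw and adjusted, stood beside it without a named test, and were used only to find which features the table holds. No S. pombe features stood in either table (0 and 0 features). The listed lengths of 99.9% of protein-coding features in both tables were multiples of 3, so lengths are coding lengths.

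The total RNA table was complete, with 6518 features. The newly synthesized RNA table held 2822 features, and its last line broke off part-way. The authors' adjusted p-values there fit ranks within 6707 features, to within 1% for 2818 of the 2821 features with a p, so the table holds the 42.1% with the lowest p-values, none above 1.64e-31. Counts in the newly synthesized RNA table, its medians and its gene list tests therefore describe that selected part. Of its features, 2821 were also in the total RNA table and 1 was not. The tables paired 33.8% of total RNA features (2206) and 41.0% of newly synthesized RNA features (1156) with a gene name, and gene lists were matched to those names, to systematic identifiers for named exceptions, or to identifier patterns.

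The choices in this paragraph were made before the data were examined. Features with a mean of at least 10 counts over the libraries of a fit were tested. Counts were fitted with edgeR 4.0.16 (quasi-likelihood F test, treatment as the only term) in R 4.3.3, once per fraction, with the authors' size factors as the scaling. The factors were 0.613 and 0.657 for newly synthesized DMSO, 1.59 and 1.56 for newly synthesized auxin, 1.09 and 0.728 for total DMSO, and 1.05 and 1.19 for total auxin. A feature was called higher or lower at a Benjamini-Hochberg adjusted p below 0.05. Median log2 fold changes over the tested features were given with the per-library medians and an exact two-sided permutation test, whose smallest possible p with 2 against 2 libraries is 0.333. An interaction of fraction and treatment was fitted over all 8 libraries for features tested in both fractions.

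Gene lists, 28 of them, were also fixed then: cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, glycolysis and ethanol fermentation, Hsf1-driven chaperones, Msn2/4 general stress, Gcn4-driven amino acid synthesis, sulfur assimilation and methionine, the phosphate regulon, multidrug resistance, the proteasome, nuclear-encoded respiration, ergosterol synthesis, histones, G1/S and G2/M cell cycle genes, alpha-cell and a-cell genes, the mating response, the iron regulon, Mediator subunits (other than Med14 and Med17), RNA polymerase II and general factors, SAGA and TFIID, mRNA decay, hexose transport and galactose, mitochondrial-encoded genes, snoRNA genes, and RNA polymerase III transcripts. Lists with at least 5 tested members were compared with all other tested features by camera (limma 3.58.1, preset correlation 0.01), also with an estimated correlation, and tested by fry, each with Benjamini-Hochberg adjustment over the lists. The pattern for RNA polymerase III transcripts also took in mitochondrial transfer RNAs, so nuclear RNA polymerase III transcripts, all features of the snoRNA biotype and all features of the mitochondrial chromosome were added as groups after the data were seen. GO terms of the deposited annotation with 10 to 300 tested genes were added then too, because few genes are named, as was an exact Mantel-Haenszel test, within 10 classes of total RNA level in DMSO, of how many members of a list stood in the newly synthesized RNA table.

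The rule for named genes, also fixed beforehand, took MED14 and MED17 first. Per fraction it then took the named features with a mean of at least 10 CPM (counts scaled to library size), a call and treated libraries that did not overlap the controls, up to 8 with the largest fall and 8 with the largest rise, and 2 members per called list (at most 8 lists) with the largest change in the list's direction. For the interaction it took the 5 largest called differences in each direction. These came from named features with a mean of at least 10 CPM in both fractions. Genes chosen after their values were seen are marked as such.

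Alternatives were other scalings (TMM, total counts and the median of ratios over S. cerevisiae features, scaling on mitochondrial counts and on SCR1 with RPR1), DESeq2 1.42.0 with the authors' size factors, other count filters, a minimum absolute log2 fold change of 1, 1 fit of all 8 libraries, the replicate number as a block, and leaving out each library in turn. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

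The tests were checked on simulated data drawn from the real DMSO means. Each gene was drawn independently, with 1 common spread per fraction and 1 set spread for the interaction. Shares of calls within each fraction came from runs without a shift of all genes, unlike the real data. Over 2822 newly synthesized RNA features, 47.8% of genes changed 1.5-fold, 98.5% of genes changed 2-fold and 100% of genes changed 4-fold were called with the right sign. The same shares were 53.7%, 92.5% and 100% over 5589 total RNA features, and 10.4%, 68.7% and 100% for the interaction over 2821 features. Unchanged genes made up 3.53%, 4.65% and 3.25% of the calls in the 3 simulations. A simulated shift of all genes was recovered as a median of -2.80 in newly synthesized RNA and -1.85 in total RNA, and 0 of 50 random lists were called in either fraction. Since the simulated genes were independent, the list result does not check camera on lists whose genes vary together.

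The length-divided values and the authors' own log2 fold changes were left out of the tests, since the counts carry the same information. A scaling on S. pombe counts was planned and not run, because the tables held no S. pombe features.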

Results

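RNA-seq measured total and newly synthesized RNA of budding yeast given auxin or DMSO for 30 min and then 4-thiouracil for 6 min. The Mediator subunits Med14 and Med17 of these cells both carried an auxin-inducible degron. Each of the 4 groups (total RNA in DMSO, total RNA in auxin, newly synthesized RNA in DMSO, newly synthesized RNA in auxin) held 2 libraries. The series asks whether the architectural part of Mediator is needed for global transcription, and the comparison of auxin with DMSO addresses this in each fraction. Counts in the total RNA table, which was complete, summed to 17491251 and 13004246 in DMSO and to 10862028 and 13970025 in auxin. Counts in the partial newly synthesized RNA table summed to 13125438 and 15744423 in DMSO and to 4817883 and 5882137 in auxin, which are sums over the 2822 listed features and not full depths. SCR1, the RNA of the signal recognition particle made by RNA polymerase III, was the most abundant feature of total RNA, with 6.10% and 6.00% of counts in DMSO and 9.84% and 9.10% in auxin. Coordinates are those of the deposited tables, build sacCer3. Values below are normalized counts (mean ± SD, n = 2) and log2 fold changes of auxin over DMSO from edgeR with the authors' size factors, unless another scaling is named.

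The target genes were examined first, although their RNA does not show whether the tagged proteins were degraded. In total RNA, MED14 (listed as RGR1, YLR071C, chromosome XII 275378 to 278626) fell from 3458 ± 296 to 1429 ± 191, a log2 fold change of -1.27 (SE 0.195, edgeR quasi-likelihood adjusted p = 1.06e-10), whereas TMM scaling gave a rise of 0.45. MED17 (listed as SRB4, YER022W, chromosome V 198812 to 200875) fell from 2541 ± 383 to 679 ± 88.4 in total RNA, a log2 fold change of -1.90 (SE 0.196, edgeR adjusted p = 1.28e-21), but was not called with TMM scaling (-0.17, adjusted p = 0.112). In newly synthesized RNA SRB4 fell from 9431 ± 1049 to 1609 ± 310, a log2 fold change of -2.55 (SE 0.261), and this turned to 0.23 with TMM scaling. RGR1 was not among the listed features of newly synthesized RNA.

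Newly synthesized RNA of every listed feature was lower after auxin. The median listed gene stood at 14.4% of its DMSO level, 6.95-fold lower, with a median log2 fold change of -2.80. Cell wall genes lay below other genes by a set test with a preset correlation (47 genes, median -3.20), and proteasome genes above them (18 genes, median -2.58; 11 rose with TMM scaling). Neither call held with an estimated correlation (adjusted p = 0.9996 and adjusted p = 0.982). Among features that met the rule for named genes, the largest falls were of NDJ1 (YOL104C, chromosome XV 116396 to 117454), a telomere protein of meiosis, and CWP2 (YKL096W-A, chromosome XI 259253 to 259531), a cell wall mannoprotein. NDJ1 fell 19.9-fold, from 1970 ± 20.8 to 99.0 ± 8.30, and CWP2 fell 18.9-fold, from 1130.5 ± 354 to 59.7 ± 8.75.

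All 2822 listed features were called lower and 0 higher by edgeR. None (0) was higher at an unadjusted p below 0.05, and 0 were higher by DESeq2. Because the table holds the authors' lowest p-values, this describes the 42.1% of features listed and not the rest. The authors' own log2 fold changes of the listed features were all at or below -2.20. The selection therefore settled these calls in advance, and the 3 counts of 0 are not separate support. Fold changes ran from -4.74 to -2.21, with quartiles of -3.01 and -2.63. The median per library was 94.1% and 106% of the DMSO mean in DMSO and 12.9% and 16% in auxin, so the difference of -2.80 was well beyond the pooled SD between replicates of 0.179 on the log2 scale. The exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. These levels rest on the authors' size factors: TMM scaling, which assumes that most genes do not change, moved the median to -0.01 and split the calls into 597 higher and 705 lower.

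**Figure D1:**
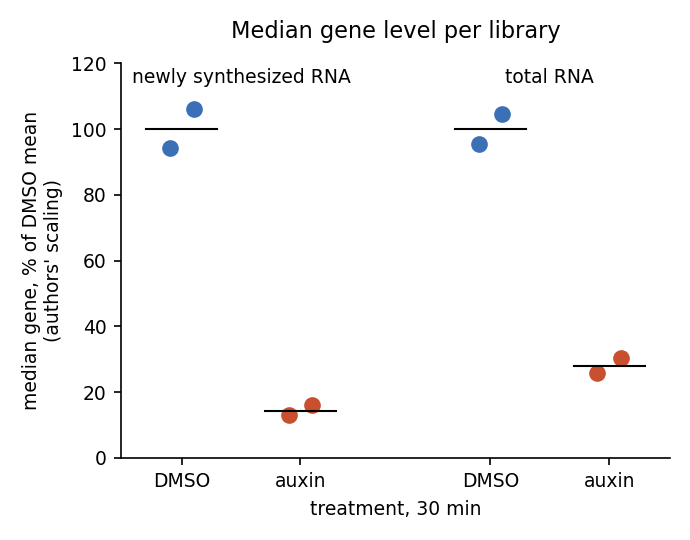
The plot shows the median gene of each library as a percent of the DMSO mean of its fraction (vertical axis, authors' scaling), with points for libraries and lines for the means of the log2 values. Auxin libraries lie at 12.9% and 16% in newly synthesized RNA (2822 listed features) and at 25.8% and 30.2% in total RNA, while with TMM scaling the medians differ by -0.01 and -0.13 on the log2 scale.

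Other large falls in newly synthesized RNA were of GAL4, the activator of galactose genes (YPL248C, log2 fold change -4.21, SE 0.217), VRP1, an actin-binding protein (-4.09, SE 0.207, a feature that overlaps 1 other), NRT1, a nicotinamide riboside transporter (-4.06), VID24, a factor in the breakdown of gluconeogenic enzymes (-3.95), MSS1, a mitochondrial transfer RNA modification protein (-3.87), and CIS3, a cell wall glycoprotein (-3.79). The 4 alpha-cell genes, among them STE3 (the a-factor receptor, -3.52) and MF(ALPHA)1 (an alpha-factor precursor, -3.46), fell with a median of -3.49, and all 4 were also lower with TMM scaling. They were too few for a set test, and the mating response list was not separated from other genes (camera adjusted p = 0.395). By the deposited annotation, 10 structural constituents of the cell wall had a median of -3.59 (camera adjusted p = 4.50e-06), 47 cell wall genes -3.20 (adjusted p = 3.85e-06), 56 genes of the extracellular region -3.19 (adjusted p = 3.50e-06), and 21 genes of membrane-anchored proteins -3.37 (adjusted p = 3.69e-08). With TMM scaling 8, 30, 34 and 16 of these genes fell and 0, 4, 4 and 1 rose. They were the 4 terms lower than other genes among 413 tested, and 9 terms, chiefly of the proteasome (15 genes of its core, median -2.57), were higher. None (0 and 0) passed with an estimated correlation, where each of the terms named had an adjusted p = 0.9996.

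Among the fixed lists, every tested member fell in newly synthesized RNA, adjusted over all listed features and adjusted over the list alone, so the lists differed in how far they fell. The 2 lists called above other genes were ribosome biogenesis factors (11 genes, median -2.52) and proteasome subunits (18 genes, median -2.58). Examples were NSR1, a nucleolar protein (-2.30, a feature that overlaps 1 other), RPA49, a subunit of RNA polymerase I (-2.35), and the proteasome subunits PUP3 (-2.28) and PRE7 (-2.38). With TMM scaling these 4 genes rose instead, as did 8 of the 11 ribosome biogenesis genes and 11 of the 18 proteasome genes, with 0 and 1 lower. The 8 snoRNA genes listed fell further (median -3.23), for instance SNR77 (-3.41) and SNR17B, a U3 RNA (-2.93), and with TMM scaling 3 of them were lower and 0 higher. Camera set the snoRNA genes below other genes (adjusted p = 9.94e-04) and ribosome biogenesis (1.05e-03) and the proteasome (9.94e-04) above them. None of these 3 calls held with an estimated correlation (adjusted p = 0.982 for each). The listed features were selected on low p-values, and 8 of 70 snoRNA genes were listed. In the lowest of 10 classes of total RNA level 8.41% of features were listed, with a newly synthesized RNA median of -3.36. In the highest class 69.8% were listed, with a median of -2.68. List and term calls in this fraction therefore cannot be told apart from an effect of this selection. Without auxin replicate 1 or without auxin replicate 2 the list called higher was mitochondrial ribosomal proteins instead of ribosome biogenesis and the proteasome, and without auxin replicate 2 the snoRNA call was also lost. Glycolysis and ethanol fermentation and the phosphate regulon were then called lower in both cases, Msn2/4 general stress without auxin replicate 1, and G1/S genes without auxin replicate 2. Hsf1-driven chaperones were also called higher without DMSO replicate 1, and cytosolic ribosomal proteins without DMSO replicate 2. With TMM scaling chaperones and mitochondrial ribosomal proteins were also called higher, and snoRNA genes were not called.

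With all 4 libraries and the authors' scaling, the remaining lists of newly synthesized RNA were not separated from other genes by camera, or had under 5 members and were not tested. Cytosolic ribosomal proteins (126 genes) had a median of -2.83, glycolysis and ethanol fermentation (11 genes) -2.85, the phosphate regulon (10 genes) -2.97, G1/S genes (9 genes) -3.01, the mating response (5 genes) -3.01, nuclear-encoded respiration (5 genes) -3.001, Msn2/4 general stress (5 genes) -2.96, and Gcn4-driven amino acid synthesis (6 genes) -2.84. Ergosterol synthesis (9 genes) had a median of -2.76, multidrug resistance (5 genes) -2.75, histones (3 genes) -2.75, mRNA decay (7 genes) -2.67, RNA polymerase II and general factors (3 genes) -2.67, the iron regulon (3 genes) -2.67, Mediator subunits (6 genes) -2.66, and SAGA and TFIID (4 genes) -2.65. G2/M genes (3 genes) had a median of -2.64, mitochondrial ribosomal proteins (17 genes) -2.62, sulfur assimilation and methionine (4 genes) -2.61, Hsf1-driven chaperones (9 genes) -2.58, and the single gene of hexose transport and galactose -3.11. With TMM scaling, where the median gene stood at -0.01, cytosolic ribosomal proteins had 18 higher and 26 lower, mitochondrial ribosomal proteins 7 and 0, chaperones 6 and 0, and G1/S genes 0 and 5. By fry, all 17 tested lists fell, an outcome that the selection of the listed features also settled. No members (0, 0 and 0) of the a-cell genes, mitochondrial-encoded genes or RNA polymerase III transcripts were listed in newly synthesized RNA.

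Since the newly synthesized table was ordered by the authors' p, membership in it was compared between lists at equal total RNA level (exact Mantel-Haenszel test, two-sided, chosen after the data were seen and adjusted over the lists). Of the tested total RNA features, 50.5% were listed. Cytosolic ribosomal protein genes were listed in 126 of 137 cases (odds ratio 7.44, adjusted p = 2.08e-13) and mating response genes in 5 of 5 (adjusted p = 0.0227). Listed less often were RNA polymerase II and general factors (3 of 17, odds ratio 0.150, adjusted p = 5.14e-03), SAGA and TFIID (4 of 20, odds ratio 0.188, adjusted p = 5.42e-03), snoRNA genes (8 of 70, odds ratio 0.145, adjusted p = 1.14e-07) and mitochondrial-encoded genes (0 of 23, adjusted p = 1.34e-07).

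In total RNA the median gene also fell, and the fall was uneven. The median stood at 27.7% of DMSO, 3.61-fold lower (log2 fold change -1.85). Over the genes also listed in newly synthesized RNA, the total RNA median was -2.07, against -2.80 in newly synthesized RNA. Selection on low p-values favours large falls in the latter. Cytosolic ribosomal protein genes had a median of 0.02, with 26 of 137 lower, 0 higher and 111 not called (132 of 137 were higher with TMM scaling). Mitochondrial-encoded RNAs had a median of 0.45, and mitochondrial ribosomal protein genes fell by a median of 2.22 on the log2 scale, or a log2 fold change of -2.22. Among features that met the rule for named genes (a mean of at least 10 CPM and no overlap of libraries), the largest falls were of MCM1 and ARR3. MCM1, a regulator of mating and cell cycle genes (YMR043W, chromosome XIII 353871 to 354731), fell 10.7-fold from 367 ± 139 to 34.5 ± 5.79. ARR3, an arsenite exporter (YPR201W, chromosome XVI 939922 to 941136), fell 10.6-fold from 349 ± 38.5 to 33.0 ± 0.379. The largest named rise was of SPO21, a spindle pole protein of meiosis (YOL091W, chromosome XV 145334 to 147163), 5.17-fold from 39.4 ± 10.4 to 199 ± 24.7.

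Of 5589 features tested in total RNA, edgeR called 5157 lower (92.3%) and 43 higher, and 389 were not called. An absolute log2 fold change of at least 1 was reached by 4597 of the falls and 27 of the rises. The quartiles of the fold changes were -2.27 and -1.28. The median gene of each library stood at 25.8% and 30.2% of the DMSO mean in auxin, a difference beyond the pooled SD between replicates of 0.131 on the log2 scale, and the exact permutation p was 0.333, the smallest possible. Summed normalized counts fell less, to 61.0% and 69.3% of the DMSO mean, as abundant genes fell least: across 10 classes of increasing level, the medians were -1.83, -2.12, -2.15, -2.12, -2.11, -2.004, -1.87, -1.69, -1.37 and -0.61. TMM scaling gave 1591 higher and 1944 lower with a median of -0.13.

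Further falls in total RNA were of OYE3, an NADPH oxidoreductase (YPL171C, -3.33, SE 0.217), MSS1 (-3.32, SE 0.247), ECM4, a glutathione transferase (YKR076W, -3.29, SE 0.208), ATR1, a multidrug efflux pump (YML116W, -3.28, SE 0.213), JIP4 (YDR475C, -3.21, SE 0.237, with uneven raw counts of 30 and 74 in the auxin libraries) and SLU7, a splicing factor (YDR088C, -3.21, SE 0.243). ATR1, JIP4 and SPO21 have a paralog noted in the deposited descriptions, and reads shared with it could not be separated here. All of these falls stayed below 0 with TMM scaling, from -1.49 for SLU7 to -1.72 for MCM1. After SPO21, the largest named rise was of HRP1 (YOL123W, chromosome XV 87844 to 89448), which encodes a subunit of the messenger RNA cleavage factor. HRP1 rose 3.84-fold from 3074 ± 78.1 to 11796 ± 1169 (log2 fold change 1.94, SE 0.206, edgeR adjusted p = 1.74e-20). SPO21 had a log2 fold change of 2.37 (SE 0.266, edgeR adjusted p = 1.15e-18).

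**Figure D2:**
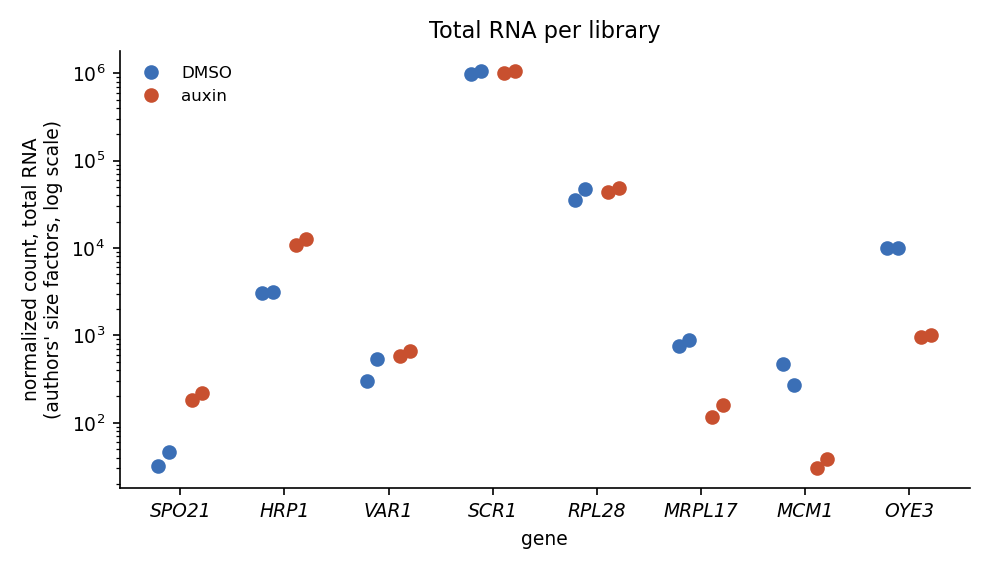
The plot shows normalized counts of 8 genes in total RNA on a log axis, with blue points for the 2 DMSO libraries and red points for the 2 auxin libraries. MCM1 lies 10.7-fold and OYE3 10.1-fold lower in auxin, SPO21 5.17-fold and HRP1 3.84-fold higher, and SCR1 has a log2 fold change of 0.02 (1.76 with TMM scaling).

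Mitochondrial-encoded genes, transcribed by their own polymerase, included 10 that rose, 0 that fell and 13 not called among 23, and 10 rose adjusted over the list alone. Those named by the rule were Q0182, a dubious reading frame (1.10, SE 0.201), Q0255, which overlaps the COX2 feature (0.64, SE 0.193, edgeR adjusted p = 9.75e-04), VAR1, a mitochondrial ribosomal protein (0.59, SE 0.191, edgeR adjusted p = 2.12e-03), and ATP6, a subunit of ATP synthase (0.47, SE 0.194, edgeR adjusted p = 0.0157). Without DMSO replicate 1 the log2 fold changes were 0.37 for Q0255 (adjusted p = 0.256), 0.21 for VAR1 (0.486) and 0.39 for ATP6 (0.227), so these 3 calls were lost, and ATP6 was also not called without DMSO replicate 2 (0.56) or without auxin replicate 2 (0.19). VAR1 was not called by DESeq2 (adjusted p = 0.186). Respiratory genes of the mitochondrial genome such as COX1 (0.23), COB (0.36) and COX3 (0.21) were not called. Q0070, Q0075, Q0110, Q0115 and Q0120, also among the 10 that rose, overlap other features. Q0110, Q0115 and Q0120 share their start, so the 10 rises are not all separate. With TMM scaling all 23 genes of the list rose. Camera placed the list above other genes (adjusted p = 1.23e-34), and the call was lost with an estimated correlation (adjusted p = 0.799). All 32 tested features of the mitochondrial chromosome, transfer RNAs included, had a median of 0.47, with 15 higher and 0 lower.

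Cytosolic ribosomal protein genes formed the largest of the fixed lists that camera set above other genes. Of 137 tested, 0 rose, 26 fell and 111 were not called (18 fell adjusted over the list alone), and with TMM scaling 132 rose and 2 fell. RPS23B (0.34, SE 0.201) and RPL40A (0.32, SE 0.202) had the highest values and were not called, whereas RPL22B (-2.33) and RPL15B (-2.13) fell. The median was 0.02 and the mean -0.16, so they differed in sign, and the median lay 1.87 above that of all genes. Camera placed the list above other genes (adjusted p = 1.81e-56), a call not kept with an estimated correlation (adjusted p = 0.954). That correlation was 0.80, estimated from 2 libraries per group. With estimated correlations no fixed list was called in either fraction, so the lost call does not set this list apart from the others. RPS23B and RPL40A have paralogs noted in the deposited descriptions, as ribosomal protein genes often do.

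By camera, snoRNA genes, glycolysis and Gcn4-driven genes also stood above other genes, but not with an estimated correlation (adjusted p = 0.954 for each). These 3 lists were not compared with genes of the same level. The most abundant of the 10 classes of level had a median of -0.61, near the glycolysis median of -0.65, so that call cannot be told apart from an effect of level. Of 70 snoRNA genes, 59 fell (58 adjusted over the list alone), 0 rose and 11 were not called, with a median of -0.85, and with TMM scaling 39 rose and 9 fell. SNR17B, a U3 RNA, fell (-0.52, SE 0.202, edgeR adjusted p = 0.0116) and SNR84 was not called (-0.08), and with TMM scaling both rose (1.20 and 1.64). SNR17B was not called without DMSO replicate 1 (-0.49), DMSO replicate 2 (-0.55) or auxin replicate 1 (-0.41). Glycolysis and ethanol fermentation had 7 of 11 genes lower (6 adjusted over the list alone) and 4 not called, with a median of -0.65; FBA1 (-0.27) and PGI1 (-0.31) were not called, TDH1 fell (-1.63), and with TMM scaling 9 of 11 rose. Gcn4-driven amino acid synthesis had 13 of 14 lower (13 adjusted over the list alone) with a median of -0.83 and 11 of 14 higher with TMM scaling. GDH1 of this list was not called (-0.21), PRO3, which overlaps 1 other feature, fell (-0.42, SE 0.191, edgeR adjusted p = 0.0291), and ARG3 fell (-2.72); PRO3 was not called without DMSO replicate 1 (-0.43), DMSO replicate 2 (-0.41) or auxin replicate 1 (-0.28). Camera placed snoRNA genes (adjusted p = 8.04e-10), glycolysis (2.83e-03) and Gcn4-driven genes (0.0294) above other genes, and none of the 3 calls held with an estimated correlation (adjusted p = 0.954 for each). The Gcn4 call was also lost without auxin replicate 2.

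Nuclear RNA polymerase III transcripts went both ways on the authors' scaling. SCR1 (0.02, SE 0.186) and RPR1, the RNA of RNase P (0.04, SE 0.200), were not called, and with TMM scaling they rose by 1.76 and 1.78. The fixed list of 15 RNA polymerase III transcripts had 6 higher (6 adjusted over the list alone), 1 lower (1 adjusted over the list alone) and 8 not called, with a median of 0.53, and 14 higher with TMM scaling; 9 of its members are mitochondrial transfer RNAs. Camera placed it above other genes (adjusted p = 3.93e-21; adjusted p = 0.426 with an estimated correlation). The 6 nuclear members had a median of 0.03, with 1 higher (snR52, 1.32), 1 lower (tL(UAG)L1, a transfer RNA, -1.82) and 4 not called, and 5 higher with TMM scaling. The spliceosomal RNAs SNR19 (U1, -0.08) and LSR1 (U2, -0.22), made by RNA polymerase II, were not called, and rose with TMM scaling by 1.65 and 1.51.

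Mitochondrial ribosomal protein genes, encoded in the nucleus, fell further than the median gene. All 36 tested fell (36 adjusted over the list alone), with a median of -2.22, for example MRPL17 (-2.56, SE 0.206) and MRPL8 (-2.49, SE 0.208), and with TMM scaling 26 fell and 1 rose. Camera placed this list below other genes (adjusted p = 1.79e-03; adjusted p = 0.954 with an estimated correlation). Annotation terms gave the same direction for mitochondrial translation (99 genes, median -2.22, camera adjusted p = 1.33e-03) and for protein kinase activity (127 genes, median -2.09, camera adjusted p = 6.70e-03), with 70 and 68 genes lower and 4 and 16 higher in TMM scaling. Terms above other genes included cytoplasmic translation (151 genes, median -0.08, 42 lower and 0 higher, camera adjusted p = 4.79e-44) and vacuolar acidification (27 genes, median -0.59, camera adjusted p = 9.63e-03), of which 135 and 18 genes rose with TMM scaling. Of 824 terms, 44 were higher and 20 lower than other genes, and 0 and 0 passed with an estimated correlation (adjusted p = 0.999 for each of the 4 named). Neither the mitochondrial ribosomal protein list nor these terms were compared with genes of the same level. Classes 2 to 5 of the 10 classes of level had medians of -2.12, -2.15, -2.12 and -2.11, and the most abundant class -0.61. The calls for the list, mitochondrial translation, protein kinase activity and vacuolar acidification therefore cannot be told apart from an effect of level.

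In the other lists almost all tested members fell in total RNA, with counts of falls the same adjusted over the list alone. The lists cover only members with a listed name, for example 5 of 20 sought for the mating response and 22 of 81 for ribosome biogenesis. Genes of the transcription machinery fell: 16 of 16 Mediator subunits (median -1.99, from CSE2 at -2.80 to SRB2 at -1.11), 20 of 20 in SAGA and TFIID (-1.95) and 15 of 17 for RNA polymerase II and general factors (-1.40), whose largest subunits RPO21 (-0.27) and RPB2 (-0.35) were not called. So did 5 of 5 mating response genes (-2.43), 6 of 6 G2/M genes (-2.28), 5 of 5 multidrug resistance genes (-2.15), 5 of 5 histones (-2.10), 17 of 17 G1/S genes (-2.001), 19 of 19 mRNA decay genes (-1.85), 21 of 21 proteasome genes (-1.79), 9 of 9 Msn2/4 genes (-1.72) and 4 of 4 alpha-cell genes (-1.71). Falls with smaller medians were of 17 of 17 respiration genes (-1.55), 13 of 13 chaperones (-1.54), 21 of 22 ribosome biogenesis genes (-1.52), 4 of 6 hexose transport and galactose genes (-1.52), 10 of 11 phosphate regulon genes (-1.39), 6 of 6 iron regulon genes (-1.31), 8 of 8 sulfur assimilation and methionine genes (-1.20) and 11 of 12 ergosterol synthesis genes (-1.18). The single a-cell gene tested was not called (-0.76). With TMM scaling the lists with the smaller falls turned in part: 7 of 8 sulfur genes, 8 of 12 ergosterol genes, 6 of 11 phosphate regulon genes, 10 of 17 polymerase II genes, 9 of 22 ribosome biogenesis genes, 6 of 13 chaperones, 3 of 6 hexose transport and galactose genes and 4 of 17 respiration genes rose, with 0, 0, 2, 1, 1, 3, 2 and 1 lower. The iron regulon had 2 higher and 2 lower of 6. Of the lists with larger falls, 4 of 5 mating response genes, 5 of 6 G2/M genes and 3 of 5 multidrug resistance genes still fell and 0 rose. Other lists had calls on both sides, higher and lower: Mediator subunits 2 and 4, SAGA and TFIID 3 and 9, the proteasome 6 and 5, G1/S genes 5 and 9, mRNA decay 4 and 6, histones 2 and 2, Msn2/4 genes 1 and 2, and alpha-cell genes 1 and 1. Alpha-cell and a-cell genes had under 5 tested members and no set test. None of the remaining lists of this paragraph was separated from other genes by camera. By fry, 23 of the 26 tested lists were lower, all but cytosolic ribosomal proteins, mitochondrial-encoded genes and RNA polymerase III transcripts.

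**Figure D3:**
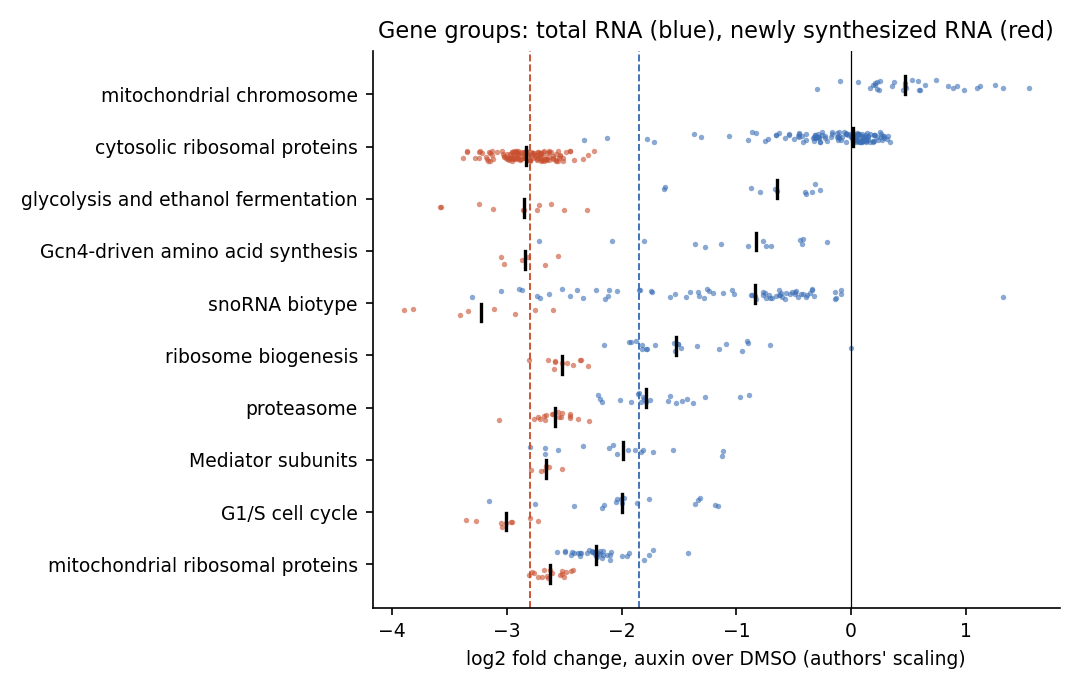
The plot shows log2 fold changes (horizontal axis, authors' scaling) of the members of 10 gene groups, in blue for total RNA and red for newly synthesized RNA, with black ticks at group medians and dashed lines at the medians of all tested features, -1.85 and -2.80. In total RNA the group medians run from 0.47 (mitochondrial chromosome) and 0.02 (cytosolic ribosomal proteins) to -2.22 (mitochondrial ribosomal proteins), and with TMM scaling 32 of 32 and 132 of 137 members of the first 2 groups rise while 26 of 36 of the last fall.

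Whether the change differed between fractions was tested as an interaction in the 2821 features tested in both. Among named features with a mean of at least 10 CPM in both fractions, the 5 largest differences were all in genes of the cytosolic ribosome. Their newly synthesized RNA fell while their total RNA was not called changed. Features without a gene name were not ranked. No gene list was tested for the interaction. RPL28 (YGL103W, chromosome VII 310967 to 311927, a feature that overlaps 1 other) had log2 fold changes of -3.03 in newly synthesized and 0.17 in total RNA, a difference of -3.19 (SE 0.275, edgeR adjusted p = 1.48e-27). RPL26B had a difference of -3.19 (SE 0.279; -2.93 and 0.25), RPL34A of -3.16 (SE 0.293; -3.28 and -0.12), RPL14A of -3.14 (SE 0.293; -3.09 and 0.05) and RPS13 of -3.11 (SE 0.280; -2.999 and 0.11).

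In all, 1537 features fell more in newly synthesized than in total RNA and 1284 were not called. For the opposite direction edgeR gave 0, with 0 at an unadjusted p below 0.05 and 0 by DESeq2. The median difference was -0.72, and 98.1% of features were lower in newly synthesized RNA. Across genes, which are not independent replicates, the changes in the 2 fractions correlated with a Pearson r of 0.405 and a Spearman rho of 0.432. The features tested were those with the authors' lowest p-values in newly synthesized RNA, which favours large falls there, and TMM scaling of each fraction gave 668 that fell more and 1305 that fell less.

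**Figure D4:**
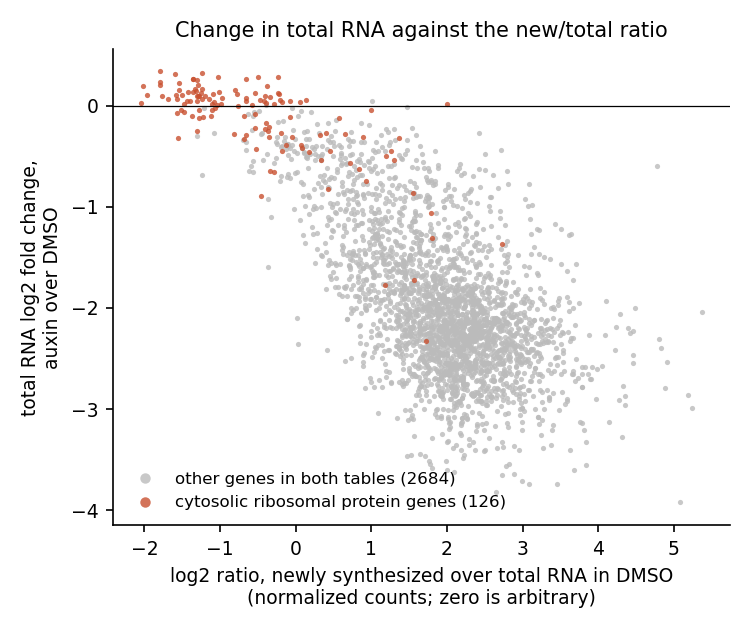
The plot shows, for genes in both tables, the log2 fold change of total RNA (vertical axis) against the log2 ratio of newly synthesized to total RNA in DMSO (horizontal axis, arbitrary zero), with the 126 cytosolic ribosomal protein genes in red among 2810 genes. Most ribosomal protein genes lie at the left with low ratios and near 0 on the vertical axis (median of all 137 tested 0.02; 132 of 137 higher with TMM scaling).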

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

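The tests on mitochondrial features, on features not made by RNA polymerase II, on overlapping features and on sporulation annotation were chosen after the results were seen. The change after auxin differed between newly synthesized and total RNA by the interaction test: 1537 features fell more and 0 less in newly synthesized RNA on the authors' scaling, against 668 and 1305 with TMM and 152 and 2399 with total counts. The features were those with the authors' lowest p-values in newly synthesized RNA. The named differences (newly synthesized minus total RNA, log2) were -3.19 for RPL28, -3.19 for RPL26B, -3.16 for RPL34A, -3.14 for RPL14A and -3.11 for RPS13.

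The fall of the median gene rests on the authors' size factors, so an error in them is a technical explanation. Such an error would shift every feature of a library alike, so it cannot make differences between features. In total RNA the features of the mitochondrial chromosome had a median of 0.47 against -1.85 for all features. SCR1 (0.02) and RPR1 (0.04), made by RNA polymerase III, stood near 0, while the 6 nuclear transcripts of that polymerase ran from -1.82 to 1.32. The fall of the median gene relative to mitochondrial RNA therefore does not depend on the size factors. A size factor error as the whole cause of the fall in total RNA is argued against only if mitochondrial RNA kept its level, which was not measured. In newly synthesized RNA the table listed 0 features that RNA polymerase II does not make, so an error in the authors' size factors and a true fall cannot be told apart there. A loss of RNA polymerase II transcription without the architectural part of Mediator is the biological explanation the design names, and auxin given to cells without degron tags was not among the samples here, so an effect of auxin itself stays untested.

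Cytosolic ribosomal protein genes as a list had a median of 0.02 in total RNA (26 of 137 fell) and of -2.83 in newly synthesized RNA. Their high level alone does not account for this: of 1000 random lists of other genes matched on level, 0 had a median as high as 0.02, and the matched medians ran from -1.43 to -0.68. Slow turnover of their transcripts is a candidate explanation, since their ratio of newly synthesized to total RNA in DMSO lay below that of matched genes, by a log2 difference of -1.89 in one pair of DMSO libraries and -1.96 in the other, with 0 of 1000 lists as low in either. Differences in turnover may also underlie the uneven fall across genes: within 10 classes of level, the total RNA fold change was lower where this ratio was higher, with median Spearman rhos across genes of -0.26 and -0.40 in the 2 pairings of separate DMSO libraries, negative in 9 and 10 of the 10 classes (-0.249 and -0.390 without ribosomal protein genes). The ratio measures synthesis and labelling at 1 time only and covers the listed genes, so decay itself was not measured. At equal level, ribosomal protein genes were listed more often than other genes (odds ratio 7.44). An effect of this unequal selection on the ratio was not tested.

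Against the general fall, 28 nuclear features rose in total RNA on the authors' scaling, of which 12 had a mean of at least 100 counts, 9 had at least 10 CPM and 6 were annotated as dubious. False calls admitted because the 5157 falls share the adjustment stay open for part of them: 18 of the 28 passed an adjustment of one-sided tests for a rise alone, between the bounds of 14 and 20 set for and against this explanation. Reads of an overlapping annotated feature are a further explanation. For the 20 that overlap no other listed feature, the coordinates leave no such feature to test. Listed lengths are coding lengths, so RNA of neighbours beyond their coding ends was not tested. Such reads are argued against for 7 of the other 8, whose overlapping feature was called lower (SRG1 beside YER081W, for example, at -1.42). They stay open for the last, which overlaps RPL12A, not called (-0.18). Overlap was more frequent among the 28 (28.6%) than among other nuclear features (10.2%, Fisher's exact p = 0.00583, two-sided). Features annotated for sporulation, spores or meiosis made up 6 of the 28 (21.4%) against 374 of 5529 others (6.76%; Fisher's exact p = 0.0102, two-sided, unadjusted), but this annotation was picked from the risen features themselves, so the test restates what was seen. A rise of such genes therefore stays an open hypothesis, and 3 of the 6 had at least 10 CPM while 354 of the 380 so annotated fell, with a median of -2.02.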

How the results depend on the processing

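The scalings on SCR1 with RPR1 and on mitochondrial counts, the restriction of total RNA to genes of the newly synthesized table, the crossed pairing of libraries and the GO terms were chosen after seeing the data. Of 143 values of summary results under alternatives, 100 kept their direction and size (counts within 1.5 times) and 43 did not. TMM and the median of ratios remove a change shared by most genes by construction, which is the cause of their shifts below. Total counts make the sums of the libraries equal. This brought the median near 0 in newly synthesized RNA (-0.0575) but not in total RNA (-1.24), and the interaction with total counts sets these 2 against each other. In newly synthesized RNA TMM, total counts and the median of ratios gave 597, 438 and 621 features higher and 705, 813 and 687 lower, with medians of -0.0095 (TMM) and -0.0575 (total counts). In total RNA they gave 1591, 379 and 1746 higher, with 1944 (TMM) and 1589 (median of ratios) lower and medians of -0.13 (TMM) and -1.24 (total counts). For the interaction they gave 1305, 2399 and 1128 features that fell less and 668, 152 and 711 that fell more in newly synthesized RNA. In the same order of scalings, these named genes turned to rises. In newly synthesized RNA, SRB4 went to 0.23, 0.19 and 0.24, PUP3 to 0.52, 0.47 and 0.53, PRE7 to 0.41, 0.36 and 0.42, NSR1 to 0.49, 0.45 and 0.50, and RPA49 to 0.43, 0.39 and 0.44. In total RNA, RGR1 went to 0.45 (TMM) and 0.54 (median of ratios), SNR84 to 1.64, 0.53 and 1.74, SNR17B to 1.20, 0.094 and 1.30, FBA1 to 1.46, 0.35 and 1.55, PGI1 to 1.42, 0.31 and 1.51, GDH1 to 1.52, 0.41 and 1.61, and PRO3 to 1.30, 0.19 and 1.39. Equal mitochondrial counts gave a total RNA median of -2.08 and equal SCR1 and RPR1 counts -1.88. Genes also in the newly synthesized table had a total RNA median of -2.07. Features that rose in total RNA numbered 22 with a mean of at least 100 counts (fewer features tested), 27 with an absolute log2 fold change of at least 1 (a stricter rule), and 0 in the fit of all 8 libraries, with 2653 lower, since that fit holds only features of both tables. Lists set higher and lower than other genes in newly synthesized RNA numbered 4 and 0 with TMM, 0 and 0 with an estimated correlation, 0 and 17 by fry, which does not compare with other genes, and 1 to 3 and 1 to 4 on leaving out a library in turn. In total RNA they numbered 0 and 0 with an estimated correlation and 0 and 23 by fry, and the lists set lower numbered 1 to 2 on leaving out a library and 2 with the replicate block. The cause was not tested for the shifts of the list counts with TMM, the leave-outs and the block. The labels give samples only a number; deviations of same-numbered libraries correlated at 0.0517 in newly synthesized and -0.117 in total RNA, and at 0.163 (DMSO) and 0.0967 (auxin) between the fractions. With the replicate block there were 2822 lower and 0 higher features in newly synthesized RNA and 5226 lower and 51 higher in total RNA. The interaction gave 2148 calls when libraries of the same treatment and number formed a block across the fractions, a pairing assumed from the numbers. The replicate block added Hsf1-driven chaperones to the lists set higher in newly synthesized RNA, and in total RNA it added the proteasome to those set lower and took Gcn4-driven genes from those set higher. Crossed numbers as a block gave 37 higher and 4982 lower in total RNA. DESeq2 gave 29 higher and 5096 lower in total RNA and 1568 interaction calls. Leaving out each library gave 30 to 47 higher and 4896 to 5197 lower in total RNA, 1128 to 2003 interaction calls, and medians of -2.96 to -2.65 and -1.96 to -1.74, where a lone library was assumed to vary like the others. Removing the count filter changed nothing in newly synthesized RNA, where every listed feature passes it, and gave 56 higher and 5278 lower in total RNA. The planned scaling on S. pombe counts was not run, as no such features were listed. Intervals and p-values rest on 2 libraries per group.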

Other observations

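The features in this part were chosen after their values were seen, and are given as values. Genes of spore formation held both directions in total RNA. YOR242C, which the deposited description calls a spore wall protein of sporulation (chromosome XV 788742 to 789857), had the largest rise of all features, 11.04-fold from 36.8 ± 4.24 to 403 ± 27.0 normalized counts (n = 2; log2 fold change 3.46, SE 0.252, and 5.18 with TMM scaling). The annotation term for ascospore wall assembly (34 genes) had 4 genes higher and 28 lower with a median of -1.32, and 13 higher and 4 lower with TMM scaling. It stood above other genes by camera (adjusted p = 6.35e-04), which was lost with an estimated correlation (adjusted p = 0.999).

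The locus of serine synthesis on chromosome V showed opposite changes of neighbouring features in total RNA. YER081W (322686 to 324095), a 3-phosphoglycerate dehydrogenase that the deposited description calls SER3, rose 2.00-fold from 792 ± 32.9 to 1587 ± 164 (log2 fold change 1.00, SE 0.189, edgeR adjusted p = 1.50e-07). SRG1 (322212 to 322762), a non-coding RNA whose transcription represses SER3 per its deposited description and which shares 77 bases with YER081W, fell from 637 ± 6.14 to 237 ± 22.6 (log2 fold change -1.42, SE 0.196, edgeR adjusted p = 7.21e-13). With TMM scaling YER081W had a log2 fold change of 2.72 and SRG1 of 0.30, so SRG1 turned. Neither was listed in newly synthesized RNA.

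Cell wall genes lay on opposite sides of other genes in the 2 fractions, but the 2 calls covered different sets of genes. In newly synthesized RNA the 47 listed cell wall genes had a median of -3.20, below other genes (camera adjusted p = 3.85e-06), and in total RNA the 78 tested had a median of -1.36, above other genes (camera adjusted p = 2.93e-03), with 66 lower and 1 higher. Both calls were lost with an estimated correlation (adjusted p = 0.9996 and 0.999). With TMM scaling 30 fell and 4 rose in newly synthesized RNA, and 13 fell and 33 rose in total RNA. The difference between the fractions was not tested for this term. The call in newly synthesized RNA cannot be told apart from an effect of the selection of listed features. In total RNA the term was not compared with genes of the same level. Genes of rotary proton pumps (16 genes) had a median of -0.36 in total RNA, with 8 lower and 0 higher (15 higher and 1 lower with TMM scaling), above other genes by camera (adjusted p = 2.34e-06; adjusted p = 0.999 with an estimated correlation). The pump genes were not compared with genes of the same level, and the most abundant class of level had a median of -0.61.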
